A study of Mus musculus with 10 samples.

How the data were processed

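RNA-seq was done on inguinal white adipose tissue, the subcutaneous fat depot of the groin, from 10 male mice on a C57/BL6J background fed chow. Per the labels, 5 mice were Cre-negative (Control, replicates 2, 3, 5, 7 and 8) and 5 were Cre-positive with PexRAP deleted in adipose tissue (PexRAP-AKO, replicates 1, 2, 3, 5 and 6). Per the labels' protocols, RNA was isolated with a lipid tissue column kit and libraries were made by the Illumina manufacturer's method from total RNA. Strandedness, read length and the Cre driver are not given in the sources used here.

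The deposited table holds raw read counts per gene, not normalized. Per the submitters' processing notes, the authors used STAR 2.0.4b, Subread with featureCounts, and edgeR. The genome build and gene annotation behind the counts are not given in the sources used here. The table had 40724 rows for 40501 gene identifiers. In it, 117 identifiers stood in more than 1 row with identical counts, and 1 row of each was kept. Of the identifiers, 99.4% were found in GENCODE M21 (GRCm38), which supplied all coordinates. Without stated strand, reads of overlapping antisense genes cannot be separated.

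Library totals ran from 11274865 to 19881168 counts. Counts were scaled by TMM in edgeR 4.0.16 under R 4.3.3, and genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 14913 genes. The main test was edgeR's quasi-likelihood F test with robust dispersion, all 10 samples and no covariate, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors of log2 fold changes were the fold change divided by the square root of F. Log2 CPM values used a prior count of 2. Single values per library were compared with exact two-sided permutation tests, whose smallest possible p with 5 against 5 is 0.00794.

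Before the data were examined, 41 gene lists of pathways, cell types and tissue quality were fixed. Of 884 listed symbols, 861 were found. Each list was tested on voom values (limma 3.58.1) with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted by Benjamini-Hochberg over the lists. Camera compares a list with all other genes, and fry tests whether its genes move one way on balance. A list score is the mean log2 CPM of its tested members. Counts of members past the threshold are given over all genes and adjusted over the list alone.

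Genes named in the text were chosen by a rule fixed before the data were examined. It took Dhrs7b, up to 12 genes per direction with the largest change among those past the threshold with a mean of at least 1 CPM and no predicted or pseudogene name, and up to 4 members per list by p. Other genes are said to be chosen after their values were seen.

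The test was tried on simulated counts for the 14913 genes of the PexRAP-AKO against Control comparison. Each gene was drawn independently with edgeR's dispersions, so correlation between genes was not simulated. It recovered 56.7% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 97.0% of those changed 4-fold. It made 175 calls, of which 9 were false (5.14%). DESeq2 made 205 calls on the same counts, of which 29 were false.

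Replicates were compared for repeated libraries by chi-square over genes, and the lowest value per degree of freedom was 7.61, so each library was kept as a separate replicate. The alternatives were other scalings, other filters, DESeq2 1.42.0, limma voom with and without sample weights, a surrogate variable (sva 3.50.0), cell type scores as covariates, the replicate number as a block, a threshold of 0.1 and leaving out each library. Other splits of the samples were drawn 100 times, the real one included.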

Results

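Inguinal white fat of 5 PexRAP-AKO and 5 Control male mice was profiled by RNA-seq, 1 library per labelled sample. PexRAP, also called ADHAPR and encoded by Dhrs7b, is the acyl/alkyl-dihydroxyacetone phosphate reductase that acts in the peroxisomal route of ether lipid synthesis. The comparison asks how its deletion in adipose tissue alters transcript levels in the depot. The libraries held 11274865 to 19881168 counts, and log2 library size did not part the groups (exact two-sided permutation p = 0.627). The labels do not say whether samples sharing a number are related. The labels state both 8 weeks of chow and an age of 8 weeks, so the age at harvest is uncertain.

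Dhrs7b (ENSMUSG00000042569, chromosome 11, 60830631 to 60860195, GRCm38) was lower in each PexRAP-AKO library than in each Control library. It stood at 82.4 ± 12.8 CPM in Control (SD, n = 5) and at 19.9 ± 2.26 CPM in PexRAP-AKO (SD, n = 5). The log2 fold change was -2.05 (SE 0.12, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.54e-05), and the exact permutation p was 0.00794, the smallest possible. The rest of the signal can come from cells of the tissue without Cre and from exons outside the deleted part, which the sources used here do not give. The call held in 24 of 24 alternatives.

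**Figure D1:**
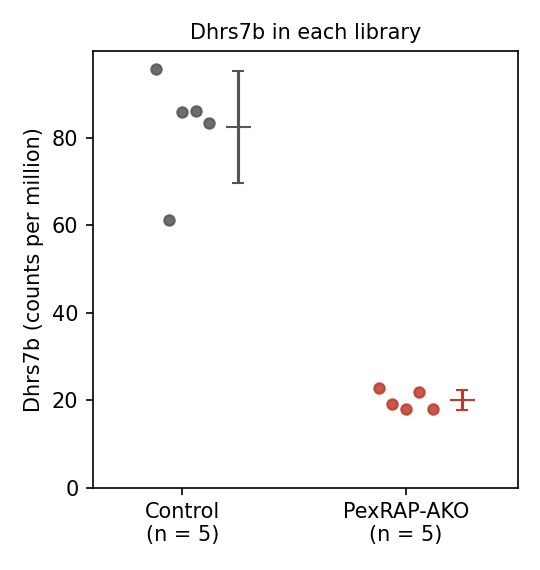
Dhrs7b in CPM (vertical axis) for each library of the Control and PexRAP-AKO groups (horizontal axis). Points are libraries and the side bars are the mean with its SD (n = 5 per group); PexRAP-AKO libraries reach at most 22.8 CPM and Control libraries at least 61.2 CPM.

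Cyp51, Lss and Msmo1, enzymes of cholesterol synthesis, rose by log2 fold changes of 1.06 (SE 0.14), 0.82 (SE 0.11) and 0.64 (SE 0.10) in PexRAP-AKO. Their calls were kept in 15, 13 and 10 of 24 alternatives. All 3 were lost without any 1 of PexRAP-AKO replicates 2 and 5 or Control replicates 2, 5, 7 and 8, and with the brown adipocyte score as a covariate, an alternative chosen after seeing the data. Their log2 fold changes over the alternatives were 0.90 to 1.22, 0.73 to 0.91 and 0.56 to 0.70. Insig1, a sterol-responsive regulator of SREBP processing, rose from 310 ± 83.3 to 694 ± 77.8 CPM (SD, n = 5 each). Acsl3, an acyl-CoA synthetase, rose from 19.02 ± 1.06 to 37.7 ± 6.97 CPM, and Lpcat3, which remodels phospholipid acyl chains, from 78.6 ± 8.58 to 149.6 ± 23.2 CPM (SD, n = 5 each). Nudt7, a peroxisomal coenzyme A hydrolase, rose by 0.57. Zfp949 (0.97), Ide (0.82), Mal2 (0.79) and Lactb2 (0.63) also rose. Of 24 alternatives, Zfp949 kept its call in 23, Acsl3 and Lpcat3 in 21 each, H2-Q10 and Mmab in 16 each, Insig1 and Ide in 15 each, Nudt7 and Lactb2 in 12 each and Mal2 in 9. H2-Q10 rose by 0.91, but it belongs to a family of near-identical genes among which reads can be split, and its level is uncertain. Mmab, an enzyme of cobalamin metabolism, rose by 0.42, and the pseudogene Gm11868, near 0 in Control, was called as well. Both lie outside the naming rule and were chosen after their values were seen.

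In all, 15 of 14913 genes passed edgeR's test, 14 higher and 1 lower in PexRAP-AKO, the lower one being Dhrs7b. At an unadjusted p under 0.05 there were 2305 genes, 1344 higher and 961 lower, against 745.65 by chance if genes were independent. Of 100 splits of the samples, the real one included, 3 gave as many, the highest other being 2521. The groups did not overlap for 3.41% of genes, against 0.794% by chance. The count depended on single libraries: it was 58 without PexRAP-AKO replicate 1, 43 without Control replicate 3, 6 without PexRAP-AKO replicates 2 or 5 or Control replicates 2 or 5, 5 without Control replicate 7 and 3 without Control replicate 8. DESeq2 called 439 genes, 309 higher and 130 lower. Of 100 splits, the real one included, 3 gave as many by DESeq2 (highest other 567, median of the others 1). In simulation its false calls were more frequent than edgeR's, but those counts used edgeR's dispersions and independent genes.

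**Figure D2:**
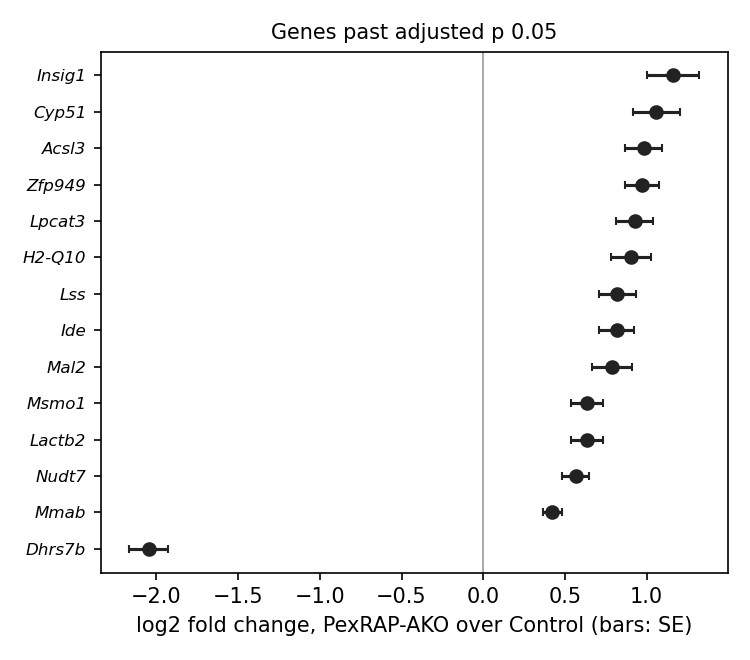
Log2 fold change of PexRAP-AKO over Control (horizontal axis) for the genes past the threshold, with SE bars; the near-zero pseudogene Gm11868 is left out. Dhrs7b is at -2.05 and the others lie between 0.42 and 1.16.

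Members of the cholesterol synthesis and SREBP2 target list stood higher together. Of 25 tested members, 24 had a positive fold change, 18 were higher when adjusted over the list alone and 3 over all genes, with a median log2 fold change of 0.64. Nsdhl (1.20, adjusted p = 0.051 in edgeR) fell just short over all genes. The list score was 4.45 ± 0.16 in Control and 5.05 ± 0.15 in PexRAP-AKO (SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0723 over the 41 lists). It passed camera at the preset correlation (Benjamini-Hochberg adjusted p = 4.27e-19) and fry (adjusted p = 0.00632), but not camera with an estimated correlation (adjusted p = 0.146).

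The de novo lipogenesis list had 14 of 22 members higher when adjusted over the list alone, 1 over all genes, with a median log2 fold change of 0.74 (fry adjusted p = 0.0325, camera preset adjusted p = 2.83e-15, adjusted p = 0.232 with an estimated correlation). Its fry call was lost without any 1 of PexRAP-AKO replicates 2, 3, 5 and 6 or Control replicates 2, 5, 7 and 8 (adjusted p = 0.0510 to 0.0906). Scd1, the stearoyl-CoA desaturase, took 4.08% to 5.33% of all counts in Control libraries and 6.56% to 8.65% in PexRAP-AKO libraries (exact permutation p = 0.00794). Its edgeR log2 fold change of 0.77 did not pass over all genes (adjusted p = 0.0733). Among LXR targets, 6 of 19 members were higher over the list alone, with a median of 0.10 and a mean of 0.36 (fry adjusted p = 0.00632, adjusted p = 0.146 with an estimated correlation). Of the 6, Scd1, Scd2 and Srebf1 are also in the lipogenesis list and Lpcat3 in the glycerophospholipid list. These lists are therefore not separate results. Abca1 (0.01), Abcg1 (0.10) and Mylip (-0.01) did not pass over the LXR list alone. They and Srebf1 were chosen after their values were seen. Scd2 was at 174 ± 84.9 CPM in Control and 736 ± 306 CPM in PexRAP-AKO (SD, n = 5, edgeR adjusted p = 0.0838). The triglyceride synthesis list had 5 of 27 members higher over the list alone (fry adjusted p = 0.0164, lost without PexRAP-AKO replicate 3 at 0.0566 or Control replicate 5 at 0.0510, adjusted p = 0.226 with an estimated correlation), and Agpat2 was at 0.95 (edgeR adjusted p = 0.0657). The polyunsaturated fatty acid list shares Fads1, Fads2, Elovl5 and Elovl6 with the lipogenesis list, Elovl5 and Elovl6 being chosen after their values were seen. It had 5 of 16 higher over the list alone, Fads1, Fads2 and Elovl5 among them (fry adjusted p = 0.0397, adjusted p = 0.232 with an estimated correlation). Its fry call was lost without any 1 of PexRAP-AKO replicates 2, 3 and 5 or Control replicates 2, 5, 7 and 8 (adjusted p = 0.0510 to 0.107). The glycerophospholipid list had 4 of 28 (fry adjusted p = 0.00632, adjusted p = 0.204 with an estimated correlation).

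Brown adipocyte markers leaned the same way as these lists, with 0 past the threshold over the list alone. They passed camera at the preset correlation, but neither fry (adjusted p = 0.262) nor camera with an estimated correlation (adjusted p = 0.463). Of 15 tested, 14 had a positive fold change, with a median of 0.78, and their scores varied widely within groups, at 4.33 ± 0.99 in Control and 5.25 ± 0.68 in PexRAP-AKO (SD, n = 5, exact permutation p = 0.135). With that score as a covariate, the fry calls of the cholesterol (adjusted p = 0.0367) and LXR (adjusted p = 0.0208) lists were kept. Those of lipogenesis (0.126), polyunsaturated fatty acids (0.126), triglyceride synthesis (0.101), glycerophospholipids (0.0949) and peroxisomal oxidation (0.148) were lost. With the skeletal muscle score as a covariate, those of lipogenesis (0.0851), polyunsaturated fatty acids (0.114) and peroxisomal oxidation (0.114) were lost. Scaling by total counts alone left only the cholesterol list past fry (0.0253), with glycerophospholipids at 0.497. Without PexRAP-AKO replicate 6 and Control replicate 8 together, also chosen after seeing the data, 0 of the 7 lists passed fry (adjusted p = 0.0549 to 0.0888).

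**Figure D3:**
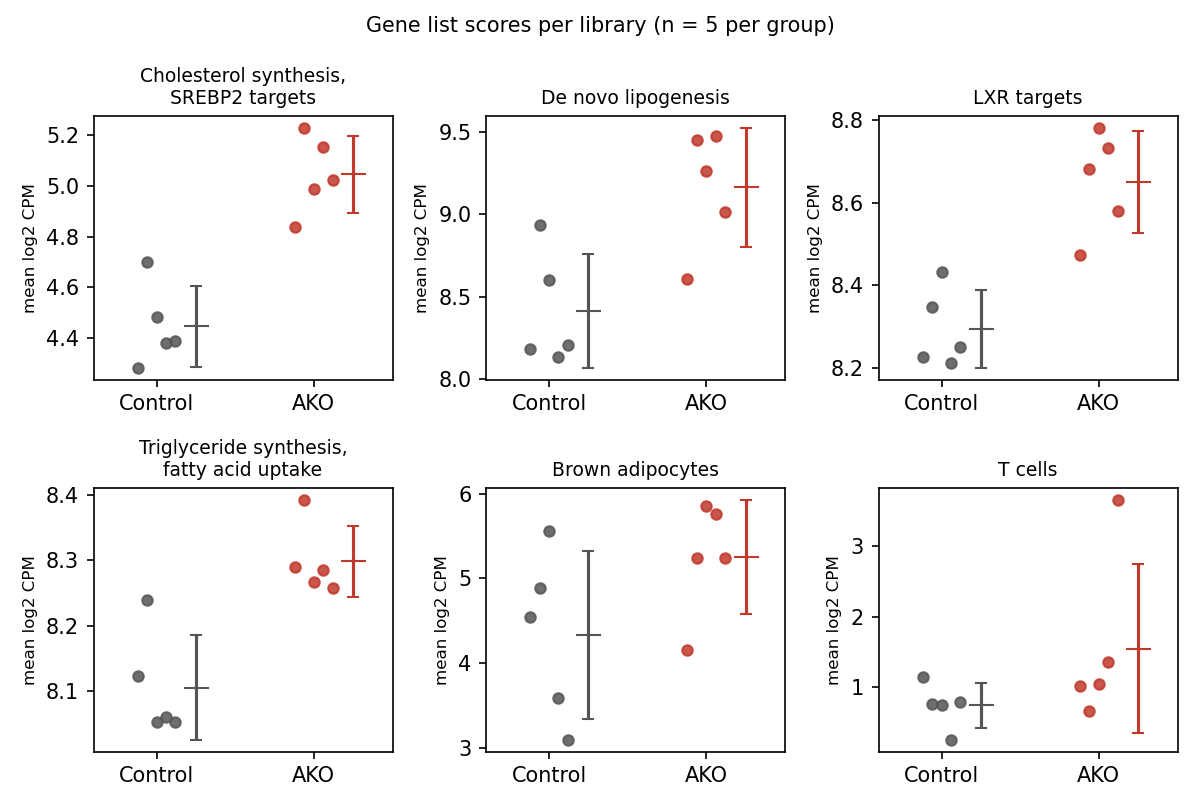
List scores, the mean log2 CPM of a list's tested members (vertical axis), for each library of Control and PexRAP-AKO (horizontal axis). Points are libraries and side bars the mean with its SD (n = 5 per group); the cholesterol synthesis scores of the groups do not overlap, and the T cell score is highest in PexRAP-AKO replicate 6 at 3.65.

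Of 50 nuclear-encoded oxidative phosphorylation genes, 43 were higher adjusted over the list alone and 0 over all genes by edgeR, with a median log2 fold change of 0.34. Mitochondrial fatty acid oxidation had 13 of 23 over the list alone, with a median of 0.30. Both passed camera at the preset correlation but not fry (adjusted p = 0.0668 and 0.0552) nor an estimated correlation (adjusted p = 0.301 and 0.275). Brown adipocyte (median 0.78) and thermogenic (median 0.53) genes stood the same way. With the brown adipocyte score as a covariate, the oxidative phosphorylation median was 0.18 and the mitochondrial fatty acid oxidation median 0.19. The peroxisomal fatty acid oxidation list passed fry (adjusted p = 0.0455, adjusted p = 0.232 with an estimated correlation) with 1 of 24 members higher over the list alone. That call was kept in 5 of 22 alternatives. It was lost with DESeq2 size factors (0.0517) and upper-quartile scaling (0.0553), and without any 1 library other than Control replicates 3 and 8 (0.0743 to 0.118).

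The ether lipid synthesis list, to which Dhrs7b belongs, had 13 tested members, and the only one to pass was Dhrs7b. Chpt1 (0.28) and Far2 (0.46) did not pass in edgeR (adjusted p = 0.225 and 0.341). Its median was 0.06 and its mean -0.11, so they differ in sign. Of 20 peroxisome biogenesis genes, 2 were higher and 1 lower over the list alone.

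Over the 41 lists, 24 passed camera at the preset correlation, 18 higher and 6 lower, 7 passed fry, all higher, and 0 passed with an estimated correlation. The preset test is permissive here: other splits of the 10 samples gave a median of 15 lists. Lists of other cell types moved in both directions. All 18 endothelial genes had a negative fold change, with a median of -0.26 and 0 past the threshold over the list alone (camera preset adjusted p = 7.84e-08, adjusted p = 0.322 with an estimated correlation). Smooth muscle (-0.22) and Schwann cell (-0.29) medians were also lower. Skeletal muscle genes had a median of -2.04 with scores from 0.80 to 5.54 in Control libraries. Lists of tissue quality also passed camera at the preset correlation, though neither fry nor an estimated correlation. Heat shock genes had a median of 0.17 (camera preset adjusted p = 0.00522, 0.347 estimated), immediate early genes -0.16 (0.0143, 0.550 estimated) and cytosolic ribosomal proteins 0.08 (0.0202, 0.659 estimated). T cell genes had a median of 1.496, which was 0.25 without PexRAP-AKO replicate 6.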

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

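Both tests on T cell transcripts were chosen after the result was seen, and the bound of the second was set with its value already known. Among 284 groups of 5 values, 14 had a library far from the other 4, and chance alone gives 14.2. In log2 CPM, Control replicate 3 stood high for G6pdx (7.42), Nudt7 (6.51) and Pex16 (7.48), and Control replicate 5 for Rps15 (7.22). Control replicate 8 was low for Ppargc1a (4.17) and high in B cell score (3.805). PexRAP-AKO replicate 1 was low for Agpat2 (10.48) and Msmo1 (4.87), and PexRAP-AKO replicate 3 for Cdh5 (7.01). PexRAP-AKO replicate 2 was high for Hadh (9.42) and in triglyceride synthesis score (8.39). PexRAP-AKO replicate 6 was high for Cd6 (3.02), in T cell score (3.65) and in mammary and skin epithelium score (2.62).

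The T cell list had a median log2 fold change of 1.496 over 10 libraries, but passed neither fry (adjusted p = 0.446) nor camera with an estimated correlation (adjusted p = 0.649), and 0 of 18 members passed edgeR over the list alone. Lymph node tissue in PexRAP-AKO replicate 6 was weighed as a cause, since its T cell (3.65), B cell (4.60) and lymph node stroma (4.62) scores were the highest of the 10. Without that library the list still passed camera at the preset correlation (Benjamini-Hochberg adjusted p = 0.0343), which by the rule of the first test goes against it as the cause of the whole call. That camera test passes a median of 15 lists in other splits, so the pass does not exclude lymph node tissue. For most of its size it stays open, because the median fell to 0.25 without the library, a value already known when the bound (a fall under 50% of the full median) was set. No test here separates T cells in the fat of that mouse from a lymph node. The lymph node stroma score rests on 3 of 10 listed genes, Ltb, Clu and Cxcl13. Ltb and Clu were highest in PexRAP-AKO replicate 6, but Cxcl13 was not (8.62 CPM, against 16.3 in PexRAP-AKO replicate 3 and 14.9 in Control replicate 8).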

How the results depend on the processing

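The brown adipocyte score as a covariate and leaving out PexRAP-AKO replicate 6 with Control replicate 8 were chosen after seeing the data. Dhrs7b kept its call in 24 of 24 alternatives (log2 fold change -2.14 to -1.96). The count of 15 genes (14 higher, 1 lower) moved with the setting: 26 (22 and 4) with no low-count filter, 439 (309 and 130) with DESeq2, 107 (88 and 19) with sample quality weights, 28 (25 and 3) with the lymph node score, 6 (5 and 1) with the skeletal muscle score, 7 (6 and 1) with the brown score, 5 (3 and 2) without both named libraries, 150 (125 and 25) with a surrogate variable and 98 (81 and 17) at an adjusted p under 0.1. The higher share was 93.3% in the main test and 70.4% with DESeq2, which kept 13 of the 15 calls. DESeq2 gave no adjusted p for 4626 genes. Gm11868 and Mal2 were among them, and the missing value was counted as a call not kept. Leaving out 1 library gave 3 (Control replicate 8) to 58 (PexRAP-AKO replicate 1) genes, 2 to 49 higher and 1 to 9 lower. Fewer libraries were fitted there, but the cause of the spread was not tested. The other called genes never changed sign. Zfp949 kept its call in 23 of 24 alternatives, Acsl3 and Lpcat3 in 21, Mmab and H2-Q10 in 16, Cyp51, Insig1 and Ide in 15, Lss in 13, Nudt7 and Lactb2 in 12, Msmo1 in 10 and Mal2 in 9. With the replicate number as a block (numbers 2, 3 and 5), 3 genes were called (2 higher), in 6 libraries. Deviations of same-numbered samples correlated at -0.02, -0.08 and 0.36, only number 5 matching its own number best, so the numbers were not taken as pairs. Of 41 lists, 24 passed camera at the preset correlation, 0 with an estimated correlation and 7 with fry. By fry, the cholesterol list passed in 20 of 22 alternatives, LXR targets in 19, glycerophospholipids in 18, triglyceride synthesis in 15, lipogenesis and polyunsaturated fatty acids in 8 each and peroxisomal oxidation in 5. These leave out limma voom, on whose values fry already runs, and DESeq2. In 2 settings 0 of the 7 passed fry: the replicate block (adjusted p = 0.189 to 0.305) and the pair of libraries left out (0.0549 to 0.0888). With the skeletal muscle score, gene Actn3 (0.16) and list skeletal muscle (0.14) reversed. With the brown score, list thermogenic and beige adipocyte genes (-0.0065) reversed, and so did the camera direction of list ether lipid synthesis (median 0.0594), which also turned without PexRAP-AKO replicate 2 (0.0542; -0.0143 to 0.0717 over libraries left out one at a time) and never passed there. Of 2398 values of 100 named genes under alternatives, 2194 stayed on their side of the threshold, 116 lost their call and 87 gained one; the cause was not tested. The simulated recovery of 56.7% at 1.5-fold limits calls of small changes.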

Other observations

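Some lists not described above also stood apart by camera at the preset correlation, though not with an estimated correlation. Glycolysis genes had a median log2 fold change of 0.31 (adjusted p = 2.78e-05 preset, 0.347 estimated), with 1 of 23 past the threshold over the list alone. Type I interferon genes had a median of 0.27, but it did not pass without PexRAP-AKO replicate 3, whose score was 5.09. Mitochondrially encoded transcripts had a median of 0.33. Adipokine and adipocyte identity genes had a median of -0.10, with Cfd at -0.47 (edgeR adjusted p = 0.135); the list did not pass without PexRAP-AKO replicates 3 or 5 or Control replicates 2, 3 or 7, left out in turn. Progenitor, macrophage and extracellular matrix lists did not pass any of the 3 list tests.

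The brown score test, the expected score from library size and the bootstrap intervals at the 3 loci were chosen after the results were seen. Other splits of the 10 samples tested whether the counts could come from any grouping. Of 100 splits, the real one included, 2 gave as many called genes as the real 15 (highest other 22), and 2 as many in 1 direction as 14 (highest other 17). Both shares lie under the 5% set beforehand, which goes against an arbitrary grouping without excluding it. A split that mixed the genotypes gave more genes than the real one, and the counts do not show which called genes are real. The highest other split put PexRAP-AKO replicates 1 and 6 and Control replicates 2, 7 and 8 on 1 side. For lists, 3 of 100 splits gave as many as 24 by the preset test (highest other 24), and 1, the real one, gave 7 by fry (highest other 1).

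The sterol synthesis list was higher in PexRAP-AKO, and 3 technical explanations were tested. For a larger share of adipocytes, the sterol score minus the adipocyte score still parted the groups (exact permutation p = 0.00794). That test adds little, since the sterol score parted them alone and the adipocyte score was not higher in PexRAP-AKO. The adipocyte score was 9.02 ± 0.14 in Control and 8.86 ± 0.20 in PexRAP-AKO (SD, n = 5, exact permutation p = 0.183). These scores go against a larger adipocyte share as the source of the rise, without excluding it. The values went against uneven thermogenic state as the source of the whole rise. With the brown score as covariate the list passed fry (adjusted p = 0.0367). Cyp51, Lss and Msmo1, whose single calls were lost, went from 1.06, 0.82 and 0.64 to 0.90, 0.75 and 0.56. The list also passed camera at the preset correlation (adjusted p = 1.47e-20, median 0.56). That pass alone carries little weight, since the preset test gave a median of 15 lists in other splits. Without the covariate, its -log10 p for the sterol list was 19.7 in the real split, against a median of 2.10 in the others. The highest other split reached 15.1, but it kept 4 PexRAP-AKO libraries on 1 side, so it still held much of the genotype difference. Library size followed the score within groups over 10 libraries (rho = 0.62, permutation p = 0.0734; r = 0.68, permutation p = 0.0334; r = 0.51 without the 2 farthest), but its slope gives -0.03 between the groups against 0.60 observed. A response of sterol genes to PexRAP loss may remain as a hypothesis, and was not tested apart from the genotype.

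Genes at 3 loci were examined for effects of the alleles rather than of PexRAP loss; Rfc4, Gm11868 and Cyb5r4 were chosen after their values were seen. Beside Adipoq (-0.18) on chromosome 16, Rfc4 was at 0.76 (edgeR adjusted p = 0.0657), and the median of the 5 other tested genes within 250 kb was 0.30, the 98.8 percentile of windows of as many neighbouring genes, with 1 of the 5 at p under 0.05. That median lay above its bound of 0.18, the 95th percentile of the windows, which was the rule set before this test. Its 95% bootstrap interval of -0.02 to 1.14 spans the bound. The limits are the lowest and highest of the 5 genes, so the interval could hardly leave the bound out. The interval therefore decides nothing. By the rule set before the test, the values go with extra copies on a transgene from that region. They rest on 5 genes and the Cre driver is not given, so background is not excluded. By the same rule, the share of genes with p under 0.05 near Dhrs7b (97.1 percentile) lay above its bound. Srebf1 (0.30, 60199089 to 60222581), a member of the lipogenesis and LXR lists, is among those genes. A wider chromosome 16 region (79.1 percentile) and the share near Zfp949 (94.1 percentile) lay below theirs. The bootstrap intervals spanned the bound in each case, which leaves segments of another strain open. Gm11868 matches Cyb5r4 at 98.0% over 1485 bases. Cyb5r4 (-0.07, start 87022014) lies on chromosome 9 with Zfp949 (88548020 to 88571061). Of 37 other tested genes near Zfp949, 4 were lower in PexRAP-AKO and 0 higher with no overlap between the groups. They were 9430037G07Rik, Mthfsl, 9330159M07Rik and Plscr4 (edgeR adjusted p = 0.0657 to 0.175), chosen after their values were seen. All but Plscr4 lie between 88595325 and 88858870. Over all tested genes, the groups did not overlap for 3.41%. The values go with a segment of another strain around Zfp949, but the genes were picked from the same window. They do not decide it, since the share set beforehand lay below its bound.

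The endothelial list had a median of -0.26 and passed camera only at the preset correlation, with 0 of 18 members past edgeR over the list alone, fry adjusted p = 0.106 and adjusted p = 0.322 with an estimated correlation. A larger share of adipocytes was tested as a cause of the lower median. The endothelial minus progenitor score differed by -0.30 (exact permutation p = 0.214), which does not show that both cell types moved alike, so it cannot be told apart from a change in endothelial cells. The adipocyte identity list had a median of -0.10, and the progenitor (-0.0018) and macrophage (0.12) medians were not lower to the same extent, values that go against a larger adipocyte share. Smooth muscle (-0.22) and Schwann cell (-0.29) medians were lower to a like extent, which goes with it. These medians do not decide the question.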
